A study of Homo sapiens and Mus musculus with 30 samples.

How the data were processed

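Gene expression was measured by bulk RNA sequencing in 30 libraries of sorted bone marrow cells, 18 human and 12 mouse, with 3 libraries in each of 10 groups. Per the labels' protocols, the human cells came from marrow and digested bone spicules recovered from collection filters. Live cells lacking CD45, CD235ab, CD31 and CD34 were sorted on CD146 (MCAM), CD271 (NGFR) and CD106 (VCAM1). The mouse cells came from digested bones of reporter animals carrying GFP under the Osx (osterix) or Ocn (osteocalcin) promoter, after exclusion of CD45, Ter119 and CD31. Sorts of CD51+ (ITGAV) and of CD45+ (PTPRC) cells were made in both species. RNA was isolated with an AllPrep micro kit and amplified with a Clontech SMARTer kit, per the labels' protocols.

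The values used were whole-number counts of reads per Ensembl gene, deposited as a separate file for each library and not normalized. The submitters' processing notes name STAR, HTSeq and the builds hg19 and mm9, and their versions and the strand setting are not given in the sources used here. Reads of overlapping, antisense or near-identical genes may therefore be shared or lost in counting. Each file ended in 5 summary lines of HTSeq, which were left out of library sizes and tests. Reads in no gene made up 32.5% to 65.4% of a human library and 33.0% to 47.9% of a mouse library. Reads aligned to several places made up 10.9% to 33.5% and 12.4% to 19.4%, and ambiguous reads 1.0% to 2.3% and 1.2% to 1.6%. The reads counted in genes came to 5.4 to 22.0 M reads in the human libraries and 13.7 to 22.0 M in the mouse libraries. All 37 mitochondrial genes were listed at 0 in every human library. Replicate libraries differed beyond sampling noise in every group, with a smallest chi-square per gene of 23.83. Separate preparations of the same sample could also exceed that noise, so each was counted as a separate sample on its label alone. The labels call them biological replicates and do not say that they came from separate donors or animals. The p-values therefore measure only the spread between these samples, which may be technical.

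Groups were taken from the sample titles. The titles describe both single-marker subsets as CD146+CD271-, whereas the design text gives CD271+CD146-, so these subsets are named here by their number of markers alone. The mouse file names carry the opposite reporter to the titles of the Osx and Ocn libraries, and every mouse direction rests on the titles. A CD271-CD146- subset named in the design text was not analysed here. Human symbols came from a GENCODE v29 table of GRCh38, used for names only because the files were made on hg19, and it named 51996 of 57773 gene IDs. These held at least 98.24% of the gene counts of each library. The mouse files do not pair their 37620 IDs with names, so mouse gene lists, and mouse-derived gene sets in the human subsets, were not run. A planned check of the Osx and Ocn titles by the genes Sp7 and Bglap was not run either, so the mouse directions could be inverted.

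Levels in CPM were computed from the deposited counts, and levels are means ± SD over 3 libraries. Differential expression was tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, filterByExpr by group with its defaults, robust dispersions and the robust quasi-likelihood F test. All libraries of a species entered a single model of group means, with 12 residual degrees of freedom in human and 8 in mouse. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 over 19426 human and 16828 mouse genes. The common biological coefficient of variation was 0.92 in human and 0.39 in mouse. Log2 folds carry a standard error from the F statistic. The comparisons were DP with DN, SP with SN, the difference between those contrasts, DP with SP, DN with SN, the mean of the 4 subsets with CD51 and with CD45, and CD51 with CD45, where DP and DN are the double-marker and SP and SN the single-marker subsets with and without CD106. In mouse, Osx was compared with Ocn, each with CD51, and their mean with CD45.

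Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and the preset inter-gene correlation, adjusted over the 23 lists of a comparison, and again with the correlation estimated from the data. The lists were HSC niche factors, marrow reticular stroma, early osteogenic, mature osteoblast and osteocyte, adipogenic, chondrogenic, pericyte and smooth muscle, fibroblast, extracellular matrix, endothelial, erythroid, granulocyte and monocyte, B and plasma cell, T and NK cell, megakaryocyte, osteoclast, interferon response, inflammatory (NF-kB), immediate early and heat shock, cell cycle, WNT and NOTCH targets, TGF-beta and BMP targets, and glycolysis and hypoxia. Genes were named by rule. The rule took the genes of the sort markers, the 5 with the largest fold each way among those past the threshold with at least 10 CPM in the higher group and no overlap of the groups, and up to 4 members of each list past the threshold with the smallest adjusted p, or else the member with the smallest p. It left out XIST, Y-linked genes, immunoglobulin and T-cell receptor segments, HLA genes and IDs without a symbol. Of the genes so chosen, those whose fold turned under another setting, or rested on a group near 0 counts, are mostly given as levels. CXCL12 falls outside the rule and was chosen after its values were seen, as were the dendritic cell genes of the closing section, which came from a marker list written before that test.

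Groups, tests, lists and the rule for names were fixed before the data were examined, as were these alternatives: DESeq2 1.42.0 without independent filtering, RLE factors, no filter on low counts, only the groups compared, the replicate number as a block, and each library left out in turn. A fit of 16 human libraries was chosen after seeing the data. It leaves out the replicate 3 libraries labelled CD51 and CD45, whose PTPRC and CXCL12 levels go against their labels. It has 10 residual degrees of freedom, 20957 genes and a biological coefficient of variation of 0.83. The list tests without each library in turn were also chosen after seeing the data. The code was tested on simulated counts with 200 changed genes. For DP against DN, edgeR recovered 0, 6, and 34.8% of genes changed by 2, 4 and 8-fold with 18 libraries, and 0, 44.8 and 74.2% with 16. For SP against SN with 16 libraries it recovered 1.5, 34.3 and 81.8%, for the difference between the CD106 contrasts 0, 4.5 and 45.5%, and for Osx against Ocn 23.9, 89.6 and 98.5%. In these 5 simulations it called 0, 4, 3, 5 and 6 unchanged genes, and DESeq2 called 45, 53, 47, 26 and 42, among 16262 to 19292 genes.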

Results

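Transcriptomes were collected from 4 human stromal subsets of bone marrow and from CD51+ and CD45+ control sorts, with 3 libraries each. The subsets carried both CD146 and CD271 with CD106 (DP) or without it (DN), or a single marker with CD106 (SP) or without it (SN). Reads counted in genes came to 10.6 to 16.8 M per library in DP, 7.2 to 10.7 in DN, 9.1 to 10.4 in SP, 5.4 to 9.1 in SN, 9.0 to 18.8 in CD51 and 9.8 to 22.0 in CD45. In mouse, cells of Osx and Ocn reporter bones, CD51+ cells and CD45+ cells were sequenced, also with 3 libraries each. These held 13.8 to 18.8 M counts in Osx, 18.2 to 22.0 in Ocn, 15.3 to 20.8 in CD51 and 13.7 to 17.2 in CD45. The 10 most abundant genes took 6.0% to 23.2% of the counts of a human library and 6.1% to 29.2% of a mouse library. The SN subset was the shallowest, and SN replicate 2, at 5.4 M counts, lay far from all other human libraries except DN replicate 2 on the second principal component, at 190 against 103 for DN replicate 2 and at most 41.9 for the rest. On the first (37.7% of the variance) SN replicates 2 and 3 lay at 69.6 and 104.1, against -102.5 to -3.9 for the other subset libraries.

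CXCL12, the chemokine that retains hematopoietic stem cells in the marrow, was abundant in all 12 subset libraries, from 6795 to 129000 CPM. It averaged 104600 ± 28890 CPM in DP, 54980 ± 37520 in DN, 74620 ± 31000 in SP and 10310 ± 5838 in SN (SD, n = 3 each). PTPRC (ENSG00000081237), which encodes the leukocyte marker CD45 excluded by the gate, averaged 129 ± 48.3 CPM in DP, 367 ± 436 in DN, 235 ± 39.4 in SP and 872 ± 603 in SN. CD51 replicates 1 and 2 had CXCL12 at 57800 and 108000 CPM and PTPRC at 112 and 110 CPM. The library labelled CD51 replicate 3 had CXCL12 at 14.5 CPM and PTPRC at 1709 CPM. CD45 replicates 1 and 2 had CXCL12 at 48.4 and 3.76 CPM and PTPRC at 1103 and 2091 CPM, whereas the library labelled CD45 replicate 3 had 99410 and 67.9 CPM. The levels of PTPRC and of CXCL12, which is not a sort gene, therefore went against the labels of both replicate 3 controls. Tests are given with all 18 libraries as labelled and with the 16 that remain without this pair, and every direction against a control drawn from all 18 rests on those labels.

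**Figure D1:**
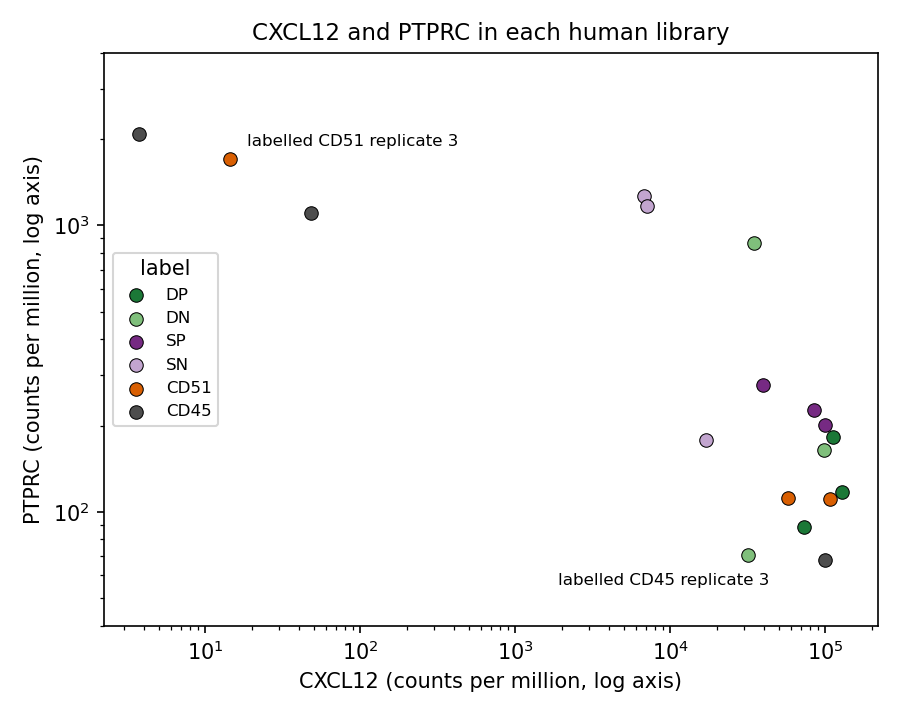
CXCL12 against PTPRC in CPM on log axes, with a point for each of the 18 human libraries coloured by label. The library labelled CD51 replicate 3 lies with CD45 replicates 1 and 2 at 14.5 CPM of CXCL12, and the library labelled CD45 replicate 3 lies with the stromal libraries at 99410 CPM.

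DP and DN were compared to ask what CD106 marks among cells carrying both CD146 and CD271. VCAM1 (ENSG00000162692), the adhesion molecule CD106 itself, averaged 4894 ± 582 CPM in DP and 2166 ± 1089 in DN (SD, n = 3), a log2 fold of 1.15 ± 0.52 (SE; adjusted p = 0.786) with 16 libraries and 1.18 ± 1.76 (adjusted p = 1) with 18. Members of the mature osteoblast and osteocyte list were lower in DP, with 0 of 9 measured genes above a fold of 0 and a median log2 fold of -2.46 (camera adjusted p = 2.12e-05). That camera call was lost with an estimated correlation (adjusted p = 0.237). Of this list BGLAP, which encodes osteocalcin, DMP1, MEPE, SOST and FGF23 did not pass the filter on low counts with 18 libraries, so the result does not cover them. Osteomodulin (OMD), a keratan sulfate proteoglycan of bone, averaged 22.3 ± 21.6 CPM in DP and 283 ± 204 in DN. IFITM5, a membrane protein of mineralizing osteoblasts, averaged 0.0434 ± 0.0752 and 6.93 ± 8.59 CPM. The early osteogenic list was not called (median -0.58, adjusted p = 0.353), and its members differed in direction. SP7, the osteoblast transcription factor osterix, averaged 1.29 ± 1.81 CPM in DP and 10.5 ± 7.40 in DN, whereas TNFRSF11B averaged 150 ± 47.7 and 48.0 ± 28.0 CPM. In the chondrogenic list, also not called (adjusted p = 0.223), chondroadherin (CHAD), a matrix protein of cartilage and bone, had 3.19 ± 1.93 CPM in DP and 111 ± 94.6 in DN, a log2 fold of -5.12 ± 2.17 (SE, adjusted p = 1).

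Lists of other marrow cells and of dividing cells were also lower in DP than in DN. The cell cycle list had a median of -1.30 over 16 genes (camera adjusted p = 3.48e-05), the erythroid list -1.44 over 15 (0.000227) and the granulocyte and monocyte list -1.22 over 16 (0.000561), each with adjusted p = 0.651 with an estimated correlation. Transferrin receptor (TFRC), which imports iron, had a log2 fold of -1.12 ± 0.49 (SE), the G-CSF receptor CSF3R -2.32 ± 0.97 and the ribonucleotide reductase subunit RRM2 -1.94, all with adjusted p = 1. No member of any of these 4 lists passed the threshold over all genes, and 0 passed when adjusted over the list alone. Among the 12 subset libraries the erythroid list stood highest in SN replicate 2 (6.73 mean log2 CPM), SP replicate 2 (6.32) and DN replicate 2 (6.11), all of the same replicate number. With 18 libraries and without DN replicate 2, the erythroid, granulocyte and cell cycle calls ended (adjusted p = 0.336, 0.235 and 0.0757), and the osteoblast call held without each library in turn, at an adjusted p of at most 0.0012. Medians of HSC niche factors (0.33) and extracellular matrix (0.39) lay above 0 where camera pointed down (adjusted p = 0.988 for both). In the 16-library fit 6 lists were called, with 0 members over all genes. Both the osteoblast (1.25e-06; 2 of 10 members fell when adjusted over the list alone) and the cell cycle list (1.38e-06; 2 of 16) were lower in DP and held without each library (adjusted p at most 0.000117 and 0.00861). The erythroid (0.000252; 1 of 15) and granulocyte (0.00123) lists were lower and ended without DN 2 (0.208 and 0.205). The osteoclast list (median -3.20, 0.0198) was lower and the adipogenic list (0.81, 0.0384) higher, and both ended without DP 1 or DN 2 (up to 0.552 and 0.205). With an estimated correlation the 6 lists had adjusted p = 0.195 to 0.452. By edgeR 0 genes passed the threshold with 18 or with 16 libraries, against 738 and 1286 at an unadjusted p under 0.05, and DESeq2 called 14 and 34. With no filter on low counts the 16-library fit called 54.

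**Figure D2:**
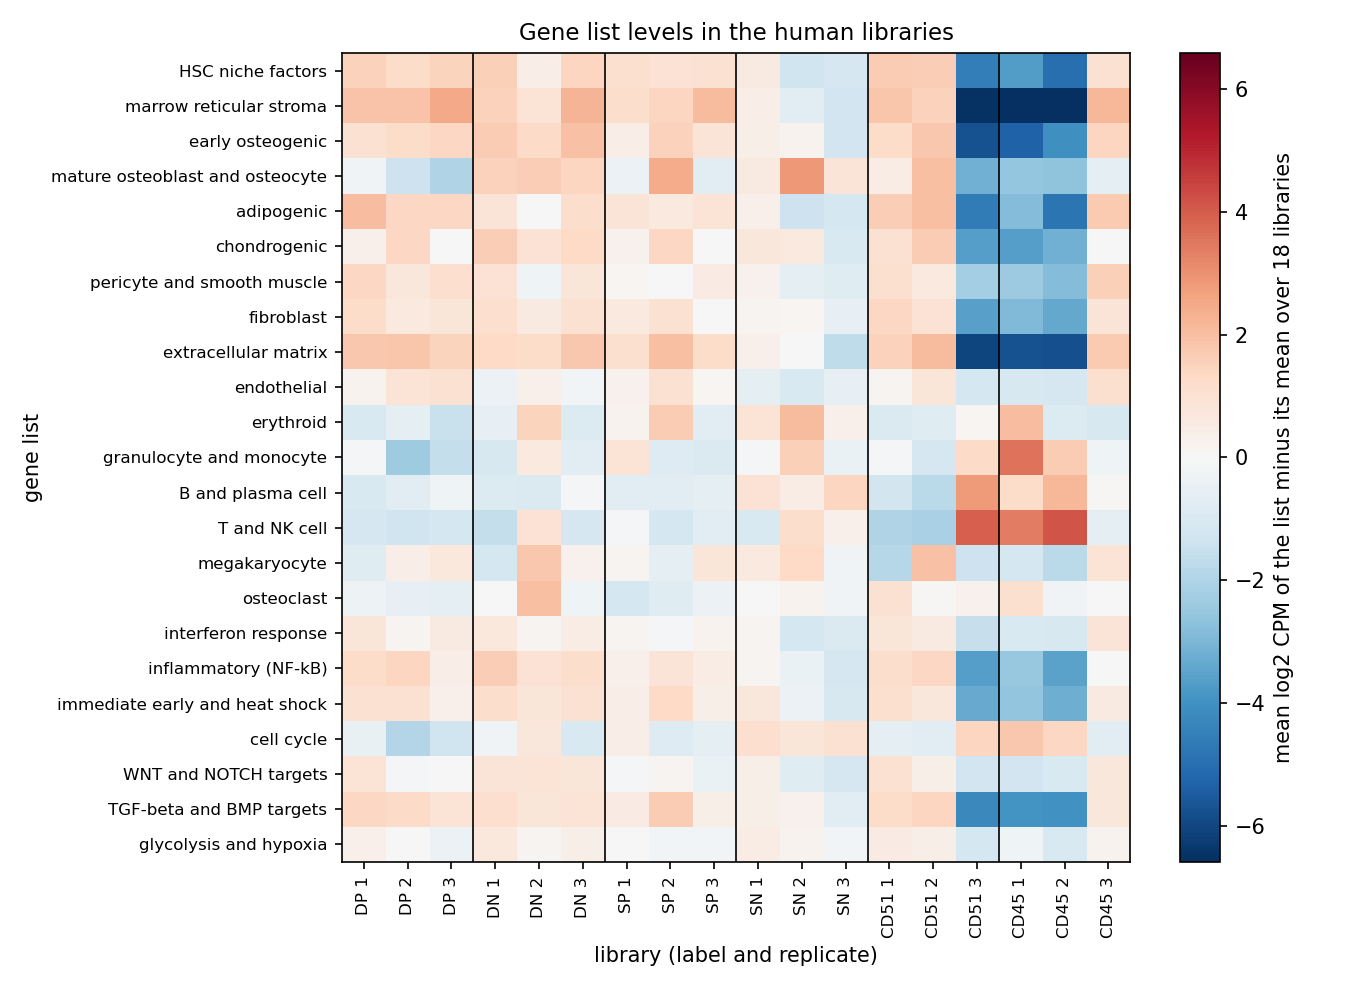
Mean log2 CPM of each of the 23 gene lists in the 18 human libraries, less the list's mean over all libraries, with red above and blue below that mean. The mature osteoblast and osteocyte list stands lower in DP than in DN, and the libraries labelled CD51 replicate 3 and CD45 replicate 3 each carry the pattern of the other control.

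SP and SN put the same question to cells sorted on a single marker, and here stromal genes were higher with CD106. On the first principal component SN 2 and SN 3 lay at 69.6 and 104.1, against -85.1 to -30.5 for SP. They thus lay towards CD45 replicates 1 and 2 (219 and 241). A lower share of stromal cells in SN 2 and SN 3 was not told apart from a difference that goes with CD106. VCAM1 averaged 4090 ± 675 CPM in SP and 645 ± 608 in SN (SD, n = 3, scaled with all 18 libraries). In the 16-library fit its log2 fold was 2.64 ± 0.55 (SE, edgeR adjusted p = 0.0223). The leptin receptor LEPR (ENSG00000116678), a marker of perivascular marrow stroma, rose by 2.79 ± 0.52 (adjusted p = 0.00987) and the vascular growth factor ANGPT1 (ENSG00000154188), a ligand of TEK, by 2.25 ± 0.47 (0.021). The transcription factor EBF3, which maintains CXCL12-abundant reticular cells, rose by 2.05 ± 0.43 and the cell adhesion molecule CHL1 (ENSG00000134121) by 2.62 ± 0.44 (0.00635). Members of the marrow reticular stroma list had a median log2 fold of 1.94 (camera adjusted p = 1.48e-07), and 4 of 13 rose over all genes and 9 when adjusted over the list alone. HSC niche factors had a median of 1.84 (3.93e-05), with 2 of 14 members up over all genes and 8 adjusted over the list alone. Both lists had adjusted p = 0.251 with an estimated correlation.

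Genes of fat and of matrix moved the same way. The adipogenic list rose with a median of 1.43 (camera adjusted p = 0.000839; 3 of 11 members over all genes, 5 adjusted over the list alone), including PPARG, the master regulator of adipogenesis, by 2.47 ± 0.46 (SE, adjusted p = 0.00987), and the adipokine ADIPOQ (ENSG00000181092) by 2.83 ± 0.53 (0.0112). The extracellular matrix list rose with a median of 1.78 (1.87e-08; 4 of 16 members, 8 adjusted over the list alone), including the collagen crosslinker LOX by 2.53 ± 0.42 (0.00557) and fibrillin-1 (FBN1) by 2.59 ± 0.46 (0.00727). Both lists had adjusted p = 0.251 with an estimated correlation. Of the early osteogenic list (median 0.90, camera adjusted p = 0.00491) 1 of 14 members rose, or 4 adjusted over the list alone. This was TNFRSF11B, which encodes the osteoclast inhibitor osteoprotegerin, by 3.02 ± 0.49 (SE, adjusted p = 0.00557). The TGF-beta and BMP targets (median 1.07, 0.0132) had 2 of 15 members up and 1 down, or 4 and 1 adjusted over the list alone. LTBP2, which binds microfibrils, rose by 2.42 ± 0.45, and SKIL, a repressor of SMAD signalling, fell by 1.96 ± 0.42. The immediate early and heat shock list (median 0.83, 0.00189) had 5 of 14 members up when adjusted over the list alone, the interferon response list (0.84, 0.0132) 3 of 16 up and 1 down, and the inflammatory (NF-kB) list (0.58, 0.0132) 0 of 13, all with 0 over all genes. With an estimated correlation these 5 lists had adjusted p = 0.279 (early osteogenic), 0.327 (immediate early) and 0.289 (the rest).

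The B and plasma cell list was higher in SN, with a median log2 fold of -2.60 for SP over SN (camera adjusted p = 0.00728; adjusted p = 0.251 with an estimated correlation), and 1 of 12 members fell over all genes and 3 adjusted over the list alone. JCHAIN (ENSG00000132465), the joining chain of secreted IgM and IgA, averaged 164 ± 80.7 CPM in SN and 14.0 ± 5.22 in SP (SD, n = 3), a log2 fold of -3.55 ± 0.59 (SE, adjusted p = 0.00573). The T and NK cell list was not called (median -0.35) and 1 of its 11 members fell. This was granzyme B (GZMB, ENSG00000100453), a serine protease of cytotoxic lymphocytes and of plasmacytoid dendritic cells, which averaged 39.7 ± 29.8 CPM against 0.906 ± 0.84 (-5.44 ± 1.08, 0.0123). SPIB (ENSG00000269404), an ETS factor of B and plasmacytoid dendritic cells, averaged 39.8 ± 37.3 CPM in SN and 0.15 in SP. The cell cycle list had a median of -0.98 with 0 of 16 members above 0 (0.000202; adjusted p = 0.289 with an estimated correlation), and 0 members passed either way. The cystine transporter SLC7A11 averaged 36.1 ± 27.2 CPM in SN and 0.672 ± 0.647 in SP (-5.72 ± 1.33).

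The other 12 lists were not called between SP and SN (camera adjusted p = 0.0565 to 0.413). Their medians were -1.10 for mature osteoblast and osteocyte, 0.73 for chondrogenic, 0.06 for pericyte and smooth muscle, 0.88 for fibroblast, 2.70 for endothelial and -0.86 for erythroid. They were -0.23 for granulocyte and monocyte, -0.35 for T and NK cell, -0.79 for megakaryocyte, -1.05 for osteoclast, 0.22 for WNT and NOTCH targets and -0.18 for glycolysis and hypoxia. The means of the chondrogenic (-0.48) and pericyte (-0.28) lists lay below 0 where median and test lay above. The osteoclast list held CTSK, a collagen-degrading protease that stromal cells also express, which rose by 2.07 ± 0.40 (SE, adjusted p = 0.0112). In the fibroblast list decorin (DCN) rose by 2.10 ± 0.45 (0.021), and in the glycolysis list PFKFB3, a regulator of glycolytic flux, fell by 1.79 ± 0.42 (0.0355).

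Of the sort genes, PTPRC (-1.88 ± 0.83, adjusted p = 0.291), NGFR (2.08 ± 0.84, 0.226) and ITGAV (1.30 ± 0.35, 0.0588) did not pass between SP and SN with 16 libraries. The edgeR test on these 16 libraries called 381 genes, 269 higher and 112 lower in SP, with a median absolute log2 fold of 2.27. All 381 differed by over 2-fold. The count was 6 without SN replicate 3 (2 higher, 4 lower) and 42 without SN 2 (17 higher, 25 lower), so the balance of directions turned there. It was 61 without SP 3, 75 without SP 2 and 1096 without SN 1, and only the libraries of both groups gave 2, both lower. DESeq2 called 1274 and no filter 1079. Leaving out each library in turn kept 6 of the 11 list calls, namely HSC niche, reticular stroma, adipogenic, extracellular matrix, B and plasma cell and cell cycle (adjusted p at most 0.0232). The other 5 ended without SN 3, and early osteogenic, inflammatory and TGF-beta lists also without SP 2 and interferon also without SN 2 (adjusted p up to 0.259). With all 18 libraries edgeR called 0 genes, against 1830 at an unadjusted p under 0.05 and 192 by DESeq2 (64 higher, 128 lower). Of 5 lists called there (reticular stroma, extracellular matrix and interferon up, B and plasma cell and cell cycle down, adjusted p = 0.00332 to 0.0445), all had adjusted p = 0.772 with an estimated correlation. Cell cycle alone kept its call without each library, and the other 4 were lost without some of SP 1, SP 2, SP 3, SN 2 and SN 3 (adjusted p up to 0.254).

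**Figure D3:**
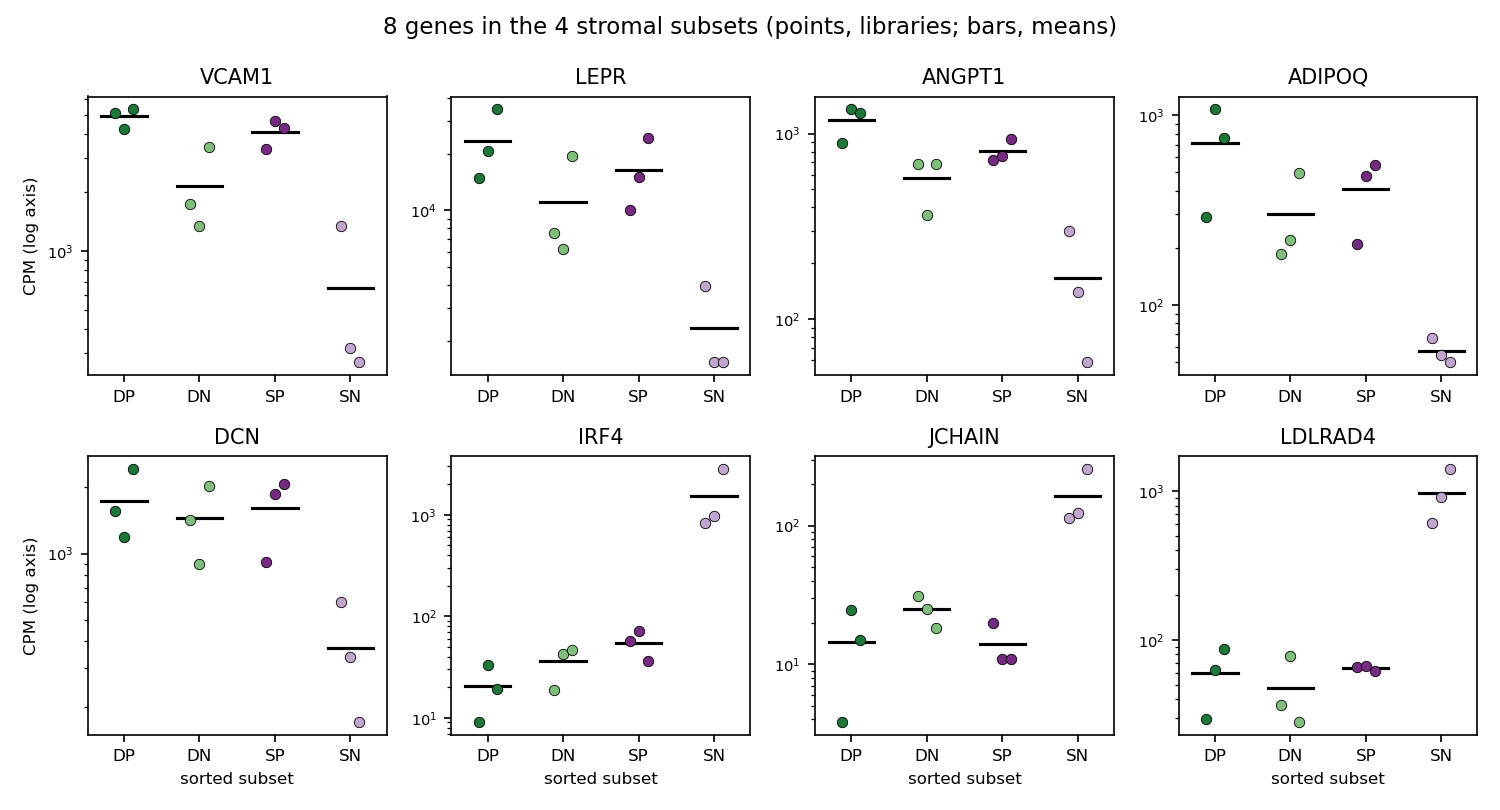
CPM on log axes of 8 genes in the 4 stromal subsets, with a point per library and a bar at the mean of 3. ADIPOQ averages 411 CPM in SP and 57.1 in SN, and IRF4, JCHAIN and LDLRAD4 stand highest in SN, at means of 1543, 164 and 979 CPM.

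Whether CD106 parted the double-marker cells as it parted the single-marker cells was tested as the difference between the contrasts. VCAM1 did not pass (log2 difference of -1.48 ± 0.73, SE, adjusted p = 0.675, 16 libraries). LDLRAD4 (ENSG00000168675), a membrane inhibitor of TGF-beta signalling, averaged 59.7 ± 28.8 CPM in DP, 47.4 ± 26.4 in DN, 64.5 ± 2.82 in SP and 979 ± 406 in SN (SD, n = 3 each). Its log2 difference of 4.22 ± 0.62 (adjusted p = 0.0161) was the 1 call of edgeR with 16 libraries, where this test on simulated counts called 5 unchanged genes, beside 1574 genes at an unadjusted p under 0.05 and 33 by DESeq2. The count fell to 0 without any of DP 2, DP 3, DN 1, DN 3, SP 1, SP 2, SP 3 or SN 3, was 78 without SN 1, 64 with no filter and 0 on the libraries of these groups alone. With 18 libraries the count was 0, against 888 unadjusted and 33 by DESeq2.

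DP and SP differ in the number of sort markers and share CD106. VCAM1 was at 4894 ± 582 and 4090 ± 675 CPM (SD, n = 3), a log2 fold of 0.26 ± 1.74 (SE, adjusted p = 1). Erythroid genes were lower in DP, with 0 of 15 above 0 and a median of -1.55 (camera adjusted p = 7.72e-08; adjusted p = 0.64 with an estimated correlation), among them GATA1, the transcription factor of the erythroid lineage, at 0.32 against 3.74 CPM. The mature osteoblast and osteocyte list had a median of -2.63 over 9 genes (0.00242; adjusted p = 0.64 with an estimated correlation), with the fibrillar collagen COL24A1 at -3.48 ± 1.31 (SE, adjusted p = 1). The cell cycle (-1.23, 6.79e-05) and granulocyte and monocyte (-1.06, 0.000323) lists were lower too, with adjusted p = 0.885 for both with an estimated correlation. In these 4 lists 0 genes passed over all genes and 0 adjusted over the list alone. The erythroid call held without each library (adjusted p at most 0.0122). The osteoblast call ended without DP 3 or SP 2 (up to 0.47), and the granulocyte and cell cycle calls ended without SP 1 (0.183 and 0.0892). With 16 libraries the same 4 lists were called lower (1.29e-07 to 0.00344), with 1 cell cycle gene down adjusted over the list alone and 0 in the others. There the erythroid and cell cycle calls held without each library (at most 0.00771 and 0.016), the osteoblast call ended without DP 3 or SP 2 (up to 0.382) and the granulocyte call without SP 1 (0.147). The pericyte and smooth muscle list was called higher (median 0.62, 0.0412) and ended without DP 1, DP 3, SP 1, SP 2 or SP 3 (up to 0.275). With an estimated correlation these 5 lists had adjusted p = 0.381 to 0.691. By edgeR 0 genes were called with 18 or 16 libraries, against 448 and 754 at an unadjusted p under 0.05 and 14 and 17 by DESeq2.

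DN and SN both lack CD106 and differ in the number of markers, and stromal genes were higher in DN. Here too a lower share of stromal cells in SN 2 and SN 3 was not told apart from a difference that goes with the markers. In the 16-library fit LEPR rose by 2.24 ± 0.51 (SE, adjusted p = 0.0456), ADIPOQ by 2.40 ± 0.52 (0.0416), LOX by 2.40 ± 0.42 (0.0143), CHL1 by 2.14 ± 0.43 (0.0307), TNFRSF11B by 2.49 ± 0.48 (0.0262) and CTSK by 2.28 ± 0.40 (0.0153). IL17RD, an inhibitor of FGF signalling, averaged 15.9 ± 9.58 CPM in DN and 0.738 ± 0.355 in SN (SD, n = 3), a rise of 4.37 ± 0.80 (0.0153). IRF4 (ENSG00000137265), a transcription factor of plasma and dendritic cells, averaged 36.0 ± 14.9 and 1543 ± 1127 CPM, a log2 fold of -5.40 ± 0.66 (SE, adjusted p = 0.00236). CLEC4C (ENSG00000198178), a lectin of plasmacytoid dendritic cells, averaged 0.57 and 62.4 ± 62.4 CPM (-6.69 ± 1.18, 0.0153), and JCHAIN fell by 2.71 ± 0.57 (0.0327). VCAM1 (1.73 ± 0.53, 0.142) and PTPRC (-1.22 ± 0.81, 0.499) did not pass.

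Of 15 lists called between DN and SN with 16 libraries, the reticular stroma list rose with 2 of 13 members over all genes and 9 adjusted over the list alone (median 1.77, camera adjusted p = 4.55e-08). For extracellular matrix these counts were 2 and 7 of 16 (1.53, 2.72e-08) and for the adipogenic list 2 and 3 of 11 (1.40, 0.000744). HSC niche factors had 0 and 6 of 14 (1.69, 6.66e-06), and the interferon response list 0 over all genes and 7 up with 1 down adjusted over the list alone, of 16 (1.06, 3.93e-05). The inflammatory (NF-kB) list had 13 of 13 members above 0 and a median of 1.34 (9.75e-06; 0 over all genes, 1 adjusted over the list alone). B and plasma cell (-2.18, 0.0036), cell cycle (-0.93, 0.00062) and erythroid (-0.95, 0.00465) lists were lower. With an estimated correlation the 15 lists had adjusted p = 0.104 to 0.409. The chondrogenic call ended without DN 3 or SN 3 (0.183), the fibroblast call without DN 1, DN 3 or SN 3 (0.0792) and the erythroid call without DN 3 or SN 2 (0.163), and 12 of the 15 held without each library. With 18 libraries 11 lists were called (0.000531 to 0.0177; 0.669 with an estimated correlation), and interferon and inflammatory alone held without each library. The other 9 ended without some of DN 1, DN 3, SN 2 and SN 3 (up to 0.253). The edgeR test called 119 genes, 78 higher and 41 lower, with a median absolute log2 fold of 2.24. The count was 4 without SN 3 (0 higher, 4 lower), 6 without DN 3 (2 and 4) and 26 without SN 2 (4 and 22), where most calls were lower, 26 without DN 1, 365 without DN 2, 815 without SN 1 and 0 on these groups alone. DESeq2 called 1007 and no filter 840. With 18 libraries edgeR called 0, against 1805 at an unadjusted p under 0.05 and 190 by DESeq2 (60 higher, 130 lower).

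The mean of the 4 subsets was set against CD51+ cells to ask what the surface markers add to a CD51 sort. With both remaining CD51 libraries, lymphocyte, erythroid and cell cycle lists were higher in the mean of the subsets. As the library labelled CD51 3 was left out for its PTPRC and CXCL12 levels, this choice itself favours higher hematopoietic and lower stromal lists in the subsets. SN weighed in that mean. The cell cycle list stood at 4.87 to 5.2 mean log2 CPM in SN and 2.15 to 3.59 in DP, against 3.42 and 3.33 in CD51 1 and 2. The T and NK cell list had a median of 1.87 with 10 of 11 members above 0 (camera adjusted p = 3.99e-06; adjusted p = 0.154 with an estimated correlation). The B and plasma cell list had a median of 1.91 with 10 of 12 members above 0 (5.06e-05) and kept its call with an estimated correlation (adjusted p = 0.0499). The B-cell antigen MS4A1 had a log2 fold of 4.02 ± 1.24 (SE, adjusted p = 1), which turned to -3.70 with all 18 libraries. The erythroid (median 1.52 with 14 of 15 members above 0, 0.000381) and cell cycle (0.49 with 16 of 16, 0.00214) lists had adjusted p = 0.361 with an estimated correlation. Over all genes 0 members of these 4 lists passed, and 1 T-cell gene and 0 others passed when adjusted over the list alone. Adipogenic (-0.91, 0.000381), extracellular matrix (-0.68, 0.00214), HSC niche (-0.56, 0.00508) and reticular stroma (-0.57, 0.00852) lists were lower in the subsets, as were interferon (-0.36, 0.0275), inflammatory (-0.45, 0.0108) and TGF-beta and BMP (-0.40, 0.0243) lists, with adjusted p = 0.361 to 0.404 with an estimated correlation. VCAM1 had a log2 fold of -1.28 ± 0.43 (adjusted p = 1). Reticular stroma stood at 8.56 to 9.17 mean log2 CPM in DP and 5.43 to 7.13 in SN, against 8.54 and 8.21 in CD51 1 and 2, so DP was not lower. The T and NK cell list was above CD51 1 and 2 (-0.6 and -0.77) in DP too (0.06 to 0.27). A lower share of stromal cells in SN 2 and SN 3 was again not told apart from a difference that goes with the markers. Without CD51 replicate 2 all but the T and NK cell and erythroid calls ended (0.0641 to 0.276), and those 2 held without each library (at most 0.0146 and 0.0385). The interferon call also ended without SN 2, SN 3 or CD51 1 (up to 0.175) and the TGF-beta call without SP 1 or SN 3. With 18 libraries, the HSC niche, reticular stroma and extracellular matrix lists were called higher in the subsets instead (adjusted p = 2.31e-05 to 0.00388; 0.69 with an estimated correlation). Their camera test pointed up where the HSC niche and matrix medians were -0.01 and -0.11, and they turned down without the library labelled CD51 3 (0.0999, 0.391 and 0.202). By edgeR 0 genes were called with 18 or 16 libraries, against 911 and 869 at an unadjusted p under 0.05 and 11 and 9 by DESeq2. With no filter 16 libraries gave 73, and with the filter the count was 2 without SN 1.

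Against CD45+ hematopoietic cells, stromal genes dominated the subsets. In the 16-library fit VCAM1 rose by 6.59 ± 0.77 (SE, adjusted p = 6.79e-06), the CD51 gene ITGAV (ENSG00000138448) by 3.87 ± 0.44 (1.73e-06) and CHL1 by 9.80 ± 0.73 (1.33e-08), and PTPRC fell by 2.35 ± 0.63 (0.024). PTPRC and CXCL12 were the genes for which the pair of control libraries was left out, so their directions are not independent evidence. CXCL12 is a member of the HSC niche list. The extracellular matrix list rose in 14 of 16 members (15 adjusted over the list alone; median 7.52), reticular stroma in 11 of 13 (12; 9.08), HSC niche factors in 11 of 14 (11; 5.89) and early osteogenic genes in 10 of 14 (11; 6.58). Targets of TGF-beta and BMP rose in 12 of 15 (15 adjusted over the list alone), among them CCN2, a matricellular protein, by 9.98 ± 0.80. Immediate early and heat shock genes rose in 12 of 14 (13; median 3.43), among them the transcription factor EGR1 (ENSG00000120738) by 7.20 ± 0.70 (2.99e-07). T and NK cell genes fell in 9 of 11 (10 adjusted over the list alone; median -4.29), among them the CD3 chain CD3G by 5.13 ± 0.44 (6.1e-08). B and plasma cell genes fell in 7 of 12 and rose in 1 (8 and 1). Lactoferrin (LTF), a neutrophil granule protein, stood at 2890 and 2593 CPM in the CD45 replicates 1 and 2 and at means of 0.262 to 14.7 CPM in the subsets.

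Of the 17 lists called with 16 libraries, 13 kept the call with an estimated correlation (adjusted p = 0.0114 to 0.0284), including adipogenic, chondrogenic, pericyte, fibroblast and inflammatory lists, with 6 of 11, 4 of 9, 4 of 11, 6 of 11 and 9 of 13 members up. Mature osteoblast (0.229), granulocyte and monocyte (0.229; 7 of 16 members down and 1 up), interferon (0.149) and cell cycle (0.149; 7 of 16 down) lists lost it. The edgeR test called 3178 genes, or 15.2% of those tested, 2002 higher and 1176 lower in the subsets with a median absolute log2 fold of 4.16. The count was 1865 without CD45 1 and 1289 without CD45 2, where the lone control is assumed to vary like the other groups. DESeq2 called 3755, 2921 higher and 834 lower, and no filter 4284, 2112 higher and 2172 lower. With 18 libraries edgeR called 0, against 2152 at an unadjusted p under 0.05 and 115 by DESeq2, and 1755 without the library labelled CD45 3. The median of all genes then lay at -0.16, or -0.14 with RLE factors, and folds are relative to that shift.

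CD51 and CD45 controls were compared without the pair of conflicting libraries. As that pair was left out for its CXCL12 and PTPRC levels, this choice itself favours directions that follow the labels. VCAM1 rose by 7.86 ± 0.85 (SE, adjusted p = 3.02e-06) and ITGAV by 4.13 ± 0.48 in CD51, and PTPRC fell by 3.86 ± 1.10 (0.0406). EBF3 rose by 10.08 ± 0.76, FBN1 by 7.20 ± 0.69, EGR1 by 7.55 ± 0.74 and PPARG by 7.38 ± 0.72, whereas CD3G fell by 6.79 ± 0.95, the interleukin-7 receptor IL7R by 5.81 ± 1.08 and the calprotectin subunit S100A8 by 4.22 ± 1.14. Matrix genes rose in 15 of 16 (15 adjusted over the list alone), HSC niche factors in 11 of 14 (11) and reticular stroma in 11 of 13 (11), and T and NK cell genes fell in 8 of 11 (9). Of 19 lists called, 13 held with an estimated correlation (adjusted p = 0.014 to 0.0459). Those lost were mature osteoblast (0.193), erythroid (0.384), granulocyte and monocyte (0.208), interferon (0.107), cell cycle (0.107) and WNT and NOTCH targets (0.138). The osteoblast call also ended without CD51 2 (0.065), the erythroid without CD45 1 (0.574) and the WNT and NOTCH call without CD51 1 or CD45 1 (0.0636). The edgeR test called 2328 genes, 1883 higher and 445 lower in CD51, and 1442 without CD51 2, 1411 without CD45 1 and 1198 without CD45 2. DESeq2 called 3527 and the libraries of both groups alone gave 3805. With 18 libraries edgeR called 0, against 305 at an unadjusted p under 0.05 and 3 by DESeq2, and VCAM1 stood at 1.11 ± 1.76 and PTPRC at -0.76, or 0.12 without CD45 2.

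Osx and Ocn reporter cells of mouse bone were compared as earlier and later osteoblast-lineage populations. As the files do not pair IDs with names, genes are given as IDs, and the directions rest on the titles, which the file names contradict. Gene ENSMUSG00000026904 was 4.14 ± 0.47 higher on the log2 scale in Osx (SE, adjusted p = 0.00123; 39.3 against 2.23 CPM) and ENSMUSG00000022860 3.98 ± 0.62 higher (0.00677; 19.1 against 1.22 CPM). ENSMUSG00000006538 fell by 4.37 ± 0.63 (0.00543; 1.47 against 31.1 CPM) and ENSMUSG00000078949 by 3.03 ± 0.53 (0.0103; 5.25 against 43.0 CPM). The edgeR test called 694 genes (4.1%), 283 higher and 411 lower in Osx, of which 597 differed by over 2-fold and 209 by over 4-fold. DESeq2 called 1532, 780 higher and 752 lower. Without Osx 1, 2 or 3 the count was 387, 160 or 187, and without Ocn 1 or 2 it was 190 or 126. Only the libraries of both groups gave 1753, 856 higher and 897 lower.

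Against mouse CD51+ cells, 832 genes passed in Osx (338 higher, 494 lower; 340 over 4-fold) and 1457 in Ocn (515 higher, 942 lower; 680 over 4-fold). DESeq2 called 1859 and 2261. The Osx count was 198 without Osx 1, 202 without Osx 2, 373 without Osx 3, 474 without CD51 1, 1621 without CD51 3 and 347 on the libraries of both groups alone. The Ocn count was 753 without Ocn 1, 634 without Ocn 2, 893 without CD51 1 and 2358 without CD51 3. Against CD45+ cells the mean of both reporters differed at 10439 genes (62.0%), 5906 higher and 4533 lower, with a median absolute log2 fold of 2.48 and 5991 genes over 4-fold. The median of all genes lay at 0.16, or 0.12 with RLE factors, and 9490 to 10970 genes passed without each library in turn.

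**Figure D4:**
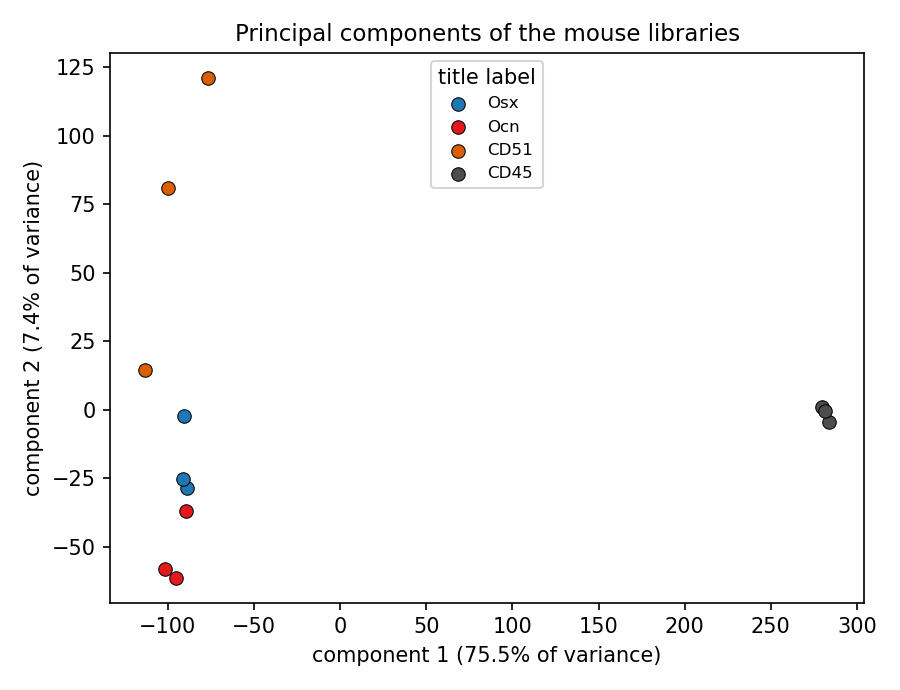
Principal components 1 (75.5% of the variance) and 2 (7.4%) of the 12 mouse libraries, with a point per library coloured by its title. The 3 CD45 libraries lie apart on component 1, at 280 to 284, and the CD51 libraries spread from 14.6 to 121 on component 2.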

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

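The 16-library fit, all tests of the replicate 3 controls and all counts of splits were chosen only after the results were seen. The test of the difference between the contrasts, DP minus DN less SP minus SN, singled out LDLRAD4 in the 16-library fit, with a log2 difference of 4.22 ± 0.62 (SE, edgeR adjusted p = 0.0161). Of 40 splits of these libraries, 5 gave at least as many genes as the 1 of the real grouping and the highest other gave 42, so chance was not excluded. On simulated counts this test also called 5 unchanged genes. With 18 libraries the real count was 0, which all 40 splits reach by construction, so that count of splits says nothing about chance (highest other 0).

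The same test singled out gene lists. It includes SN, where a lower share of stromal cells was not told apart from a difference that goes with CD106. With 18 libraries the median log2 difference was -1.22 for extracellular matrix, 0.46 for B and plasma cell, -0.90 for interferon response, -0.92 for inflammatory (NF-kB) and -1.03 for immediate early and heat shock genes. All 5 had a camera adjusted p of 0.0497, or 0.889 with an estimated correlation, and 0 of the 5 kept the call without each library in turn (adjusted p up to 0.359). With 16 libraries 10 lists were called, at a camera adjusted p of 3.31e-06 to 0.0278, or 0.287 to 0.312 with an estimated correlation. Their medians were -1.30 for HSC niche factors, -1.41 for marrow reticular stroma, -1.46 for early osteogenic, -1.99 for mature osteoblast and osteocyte and -1.22 for extracellular matrix genes. They were 0.39 for B and plasma cell, -0.90 for interferon response, -0.93 for inflammatory (NF-kB), -1.03 for immediate early and heat shock and -1.34 for WNT and NOTCH target genes. In these lists 0 members passed over all genes, and when adjusted over the list alone 2 matrix genes fell and 3 B-cell genes rose with 16 libraries. The niche (adjusted p at most 0.0143), reticular (0.00398), early osteogenic (0.0154), matrix (0.00398) and immediate early (0.0154) lists kept the call without each library. The osteoblast call ended without DP 3, DN 1, SP 2, SN 1 or SN 3 (adjusted p up to 0.372) and the B and plasma cell call without DN 1, DN 2 or SN 3 (0.0639). The interferon call ended without DN 1, SN 2 or SN 3 (0.11), the inflammatory without SN 3 (0.0639) and the WNT and NOTCH call without DP 3, SP 2 or SN 3 (0.0983).

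Outside the gene counts, reads aligned to several places made up 33.5% of the library labelled CD45 replicate 3 and 10.9% to 19.7% of the other human libraries.

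The replicate 3 controls each carried the profile of the other sort. Both, or 2 of the pair, correlated better with the other sort than with their own label, which is what an exchange of their labels would give: the library labelled CD51 3 had r = 0.94 and 0.93 with CD45 1 and 2, and the library labelled CD45 3 had 0.89 and 0.92 with CD51 1 and 2 against 0.67 and 0.65 with CD45 1 and 2. The library labelled CD45 3 also had r = 0.93 with DP 1 and 0.92 with DP 3 and SP 3. These correlations therefore cannot tell the CD51 sort from another stromal sort. A mixture of stromal and hematopoietic cells in the library labelled CD51 3 is argued against by 37 stromal list genes, whose median there was 0.0942% of that in CD51 1 and 2 (quartiles 0.00428% to 0.674%) where a bound of 10% was set. In the library labelled CD45 3, 28 hematopoietic list genes had a median of 8.78% of CD45 1 and 2 (quartiles 1.92% to 21.4%, against medians of 5.60% and 2.10% in CD51 1 and 2), and as the upper quartile passed 10%, a mixture there stays open. An exchange may account for both libraries, no biological explanation was tested, and the libraries were not reassigned.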

How the results depend on the processing

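The 16-library fit and the list tests without each library were added after the results were seen. With 18 libraries edgeR called 0 genes in every human comparison, and 2-fold changes were rarely recovered at this depth and spread (0% for DP against DN), with SN the shallowest at 5.4 M counts. The cause of each change was not tested, except that a fit of fewer groups or libraries has fewer samples. The counts of edgeR calls with RLE factors stayed within 1.5 times the TMM counts in all comparisons.

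DESeq2 called 14 genes for DP against DN, 192 for SP against SN, 33 for the interaction, 14 for DP against SP, 190 for DN against SN, 11 and 115 for the subsets against CD51 and CD45 and 3 for CD51 against CD45, where edgeR called 0. In mouse it called 1532 for Osx against Ocn, 1859 for Osx and 2261 for Ocn against CD51. With no filter edgeR called 13 for SP against SN, 6 for DN against SN, and 9 and 130 for the subsets against CD51 and CD45. Only the groups compared gave 2 for SP against SN, 44 for the subsets against CD45, 1753 for Osx against Ocn and 347 for Osx against CD51. The 16-library fit gave 381 for SP against SN, 1 for the interaction, 119 for DN against SN, 3178 for the subsets against CD45 and 2328 for CD51 against CD45. Leaving out each library gave 0 to 2 for SP against SN and 0 to 1 for DN against SN (both highest without SN 1). It gave 0 to 1755 for the subsets against CD45 (highest without the library labelled CD45 3), and 0 in the other human comparisons. In mouse it gave 126 to 520 for Osx against Ocn, 198 to 1621 for Osx and 634 to 2358 for Ocn against CD51, and 9490 to 10970 for the reporters against CD45.

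Replicate numbers were also fitted as a block, although the labels do not say that they pair the samples, and a pairing of the subsets stays open. Same-numbered human libraries had deviations correlated over 0.1 in 17 of 45 pairs (-0.79 to 0.35) and mouse libraries in 0 of 18 (-0.16 to 0.06). Among the 4 subsets 9 of 18 pairs passed 0.1 (-0.02 to 0.23), with all 3 of DP with SN, at 0.14, 0.12 and 0.12. Only SP with SN of replicate 1 lay below 0 among these 18. The erythroid list was highest in replicate 2 and lowest in replicate 3 of each subset (3.98 and 3.16 mean log2 CPM in DP, 6.11 and 3.75 in DN, 6.32 and 3.97 in SP, 6.73 and 4.99 in SN). A shared effect of the replicate number is therefore not excluded, and the main fit does not model it. With the block edgeR called 372 for Osx against Ocn, 397 and 959 for Osx and Ocn against CD51, 10018 for the reporters against CD45 and 0 in all human comparisons with 18 libraries. With 16 it called 410 for SP against SN, 142 for DN against SN, 3145 for the subsets against CD45, 2657 for CD51 against CD45, 1 for the interaction and 0 in the rest. Of 71 list calls with 18 libraries, 64 were kept. Those lost were all 5 of the interaction (0.0667 to 0.0681), reticular stroma for SP against SN (0.055) and pericyte for the subsets against CD45 (0.0525).

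With 18 libraries 71 list calls were made, 45 up and 26 down. An estimated correlation left 0, and the 16-library fit made 94, of which 63 were shared. Against CD51, 8 lists turned from up to down. In the 16-library fit their adjusted p was 0.00508 for niche factors, 0.00852 for reticular stroma, 0.132 for early osteogenic, 0.293 for chondrogenic, 0.00214 for matrix, 0.0108 for inflammatory, 0.1003 for immediate early and 0.0243 for TGF-beta genes. Without CD51 3 alone these were 0.0999, 0.391, 0.395, 0.669, 0.202, 0.0664, 0.353 and 0.177, and the lowest without another library were 5.25e-06, 5.06e-08, 3.4e-08, 0.00126, 1.62e-08, 5.25e-06, 1.87e-08 and 5.06e-08. The erythroid list of CD51 against CD45 turned without CD45 1 (0.103; 0.00275 to 0.226 over the libraries left out). Among named genes, PTPRC of the subsets against CD51 turned from -1.04 to 1.5 and CD79B from -5.92 to 1.04, both without CD51 3 and in the 16-library fit (lowest without a library -1.53 and -6.50), and VCAM1 from -0.71 to 0.30 without CD51 2 (lowest -1.28). CD3E and MS4A1 stood at -2.99 and -3.70 with 18 libraries. VCAM1 against CD45 turned from 0.40 to -0.18 without CD45 1 and -0.19 without CD45 2 (highest 6.59). PTPRC turned from -1.51 to 0.15 for DP against DN without DN 2 (lowest -1.99) and from -0.76 to 0.12 for CD51 against CD45 without CD45 2 (lowest -3.30). COL6A3 of CD51 against CD45 turned from 6.35 with 16 libraries to -0.14 with 18. Of 112 gene results named from the 16-library fit, 93 with an unchanged direction and COL6A3 of CD51 against CD45 were no longer past the threshold with 18 libraries, as were 54 on the groups compared alone, 6 with the block, 4 with no filter, 3 by DESeq2 and 1 with RLE factors. Over the fits without a library, 210 such results were no longer past it, 5 newly passed and 667 stayed on their side.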

Other observations

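The tests of explanations, the comparisons across genes and the counts of other splits given here were chosen only after the results that prompted them were seen. For the plasmacytoid dendritic test the marker list and its bounds were written before its own values. The edgeR counts of the real groupings with all libraries and the list tests on them were planned. The CD106 contrast was set side by side in double-marker and single-marker cells, whose libraries are separate. Across 8030 genes with a mean of at least 10 CPM in the 16-library fit, the log2 folds of DP over DN and of SP over SN had r = 0.54, and 69.2% had the same sign (0.54 and 69.0% across 8158 genes with 18 libraries). Of 350 genes called between SP and SN among them, 325 had the same sign between DP and DN, with a median there of 0.66 for those higher in SP and -0.51 for those lower. For the number of markers, DP over SP and DN over SN had r = 0.42 with 66.8% of the same sign, and 97 of 112 genes called between DN and SN kept their sign, with medians of 0.36 and -0.50. These correlations run across genes, which are not independent replicates, and the test of the difference between the CD106 contrasts called 1 gene. Among the subset libraries PTPRC was highest in SN 2 (1271 CPM), SN 3 (1167) and DN 2 (868), all sorted without CD106. A lower share of stromal cells in these libraries could give the same sign in both CD106 contrasts, and this was not tested.

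Some genes of plasmacytoid dendritic cells, which produce type I interferon, were higher on average in SN, with SN replicate 3 often the highest. Toll-like receptor 7 (TLR7), a sensor of viral RNA, averaged 41.2 ± 48.5 CPM in SN (SD, n = 3; 5.07, 22.3 and 96.3 in replicates 1 to 3, against a mean of 7.57 in DN) and its log2 fold over the mean of DP, DN and SP was 3.18 ± 0.79 (SE, edgeR adjusted p = 0.0222). The sphingomyelinase SMPD3 averaged 26.0 ± 21.9 CPM (28.6, 2.93 and 46.4 in the same order, against a mean of 9.88 in DN; 3.71 ± 0.79, 0.00663). The receptor LILRA4 averaged 10.3 ± 10.6 (6.75, 1.95 and 22.3), against 4.79 ± 7.08 in SP, 0.224 in DP and 0.0366 in DN (4.77 ± 1.11, 0.0123), and the exonuclease PLD4 7.95 ± 6.11 (12.9, 1.14 and 9.78; 5.46 ± 1.29, 0.0129). MAP1A, also on the marker list, averaged 122 ± 46.3 CPM in SN and 52.5 to 95.5 in the other subsets. It stood at 5.41 and 15.9 CPM in CD45 replicates 1 and 2, so its rise need not come from hematopoietic cells.

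RNA of plasmacytoid dendritic cells in the SN libraries is a candidate explanation of the dendritic cell genes higher in SN than in SP: on a list of 14 markers written before the test, none of them in another list, 10 of 11 measured were higher in SN, with a median log2 fold of 3 (the median over genes; quartiles 1.15 to 4.24), and 5 rose over all genes and 7 adjusted over the list alone. Without SN 3 the median was 1.59 (quartiles 0.44 to 3.04, 8 of 9 above 0) and 0 rose, and without another subset library it was 2.83 to 3.68. A lower share of stromal cells raising all hematopoietic genes alike stays open, as the difference of 2.36 from the granulocyte and monocyte median of 0.64 (95% bootstrap interval over genes 0.13 to 4.14, 10000 resamples) was 0.62 without SN 3 (-0.89 to 2.45), and its interval also held 0 without DP 1 (from -0.26), DN 2 (-0.37), SP 1 (-0.17) or SN 1 (-0.14). In CD45 replicates 1 and 2 LILRA4 stood at 0.0615 and 0.0387 CPM, DNASE1L3 at 0.0308 and 0.116 and SMPD3 at 1.4 and 0, below every SN library. TCL1A, at 10.1 and 38.3 CPM, lay above every SN library, and PLD4, TLR7 and LAMP5 overlapped with SN. The markers therefore do not all point one way on this explanation. RNA of B and plasma cells, whose list had a median of 2.62 (erythroid 1.42, T and NK cell 0.57), stays open too. The gate against CD45 would remove such cells. PTPRC was at 178 CPM in SN 1, under the SP range (200 to 278), but at 1271 in SN 2 and 1167 in SN 3. Those levels lay above every SP and DN library (DN 70.4 to 868). The fold between SP and SN did not pass (edgeR adjusted p = 0.291). PTPRC therefore does not argue against CD45+ cells in SN 2 and SN 3. A difference of the sorted stromal cells themselves stays open as untested.

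The osteoblast and osteocyte list was lower in DP than in DN, while DN replicate 2 also carried erythroid and granulocyte genes. Bystander hematopoietic cells in that library as the cause are argued against by the list's median without it, -2.57 (quartiles -2.91 to -1.92, 10 of 10 members below 0, camera adjusted p = 4.15e-05). With all libraries that call was lost with an estimated correlation (adjusted p = 0.237), so the median and levels carry the argument. Without DN 2 the erythroid, granulocyte and cell cycle medians were -0.32, -0.13 and -0.61. The list stood at 4.14 to 4.35 mean log2 CPM in the DN libraries and 0.74 to 2.48 in DP, and why the sorts differ in it was not tested.

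Other splits of the same libraries into groups of the same sizes were counted. Human comparisons of 3 libraries with 3 allow 10 splits, too few for a share under 0.05, and where the real count is 0 every split reaches it, so that the count of splits says nothing about chance. With 18 libraries DP against DN, SP against SN, DP against SP and DN against SN gave 0 genes for the real grouping and 0 for the highest other split, and so did DP against DN and DP against SP with 16. With 16 libraries SP against SN gave 381 and the highest other 0, whereas DN against SN gave 119 and another split, which exchanges DN 2 and SN 1, gave 272 (2 of the 10 splits as large). CD51 against CD45 gave 0 with 18 libraries, and the split that exchanges the replicate 3 libraries gave 4073, which points to a structure of the samples. The subsets against CD51 gave 0 with a highest other of 8, and against CD45 0 with 244, and all 40 splits reach a count of 0 by construction. In mouse, Osx against Ocn gave 694 and the highest other 0, Osx against CD51 832 and 1, and Ocn against CD51 1457 and 3, again over 10 splits. The reporters against CD45 gave 10439 genes in 1 of 84 splits, the real one, and at most 6907 in the others, where Ocn and CD45 were exchanged. No other split of these libraries thus reached the real count. As the labels do not say that the libraries came from separate animals, this does not exclude chance between animals.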
